A study of Mus musculus with 4 samples.

How the data were processed

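RNA was measured in bulk from colonic eosinophils of wild-type C57Bl/6 mice that drank water or received dextran sulfate sodium (DSS), with 2 libraries per group. Per the labels' protocols, poly-A RNA was selected with oligo-dT beads, fragmented and primed with random hexamers, and the libraries were sequenced on an Illumina NovaSeq X Plus. The protocol text does not say whether strand was kept, so reads of a gene and of an overlapping antisense gene are not separable here. How the eosinophils were isolated, and how pure they were, is not given in the sources used here.

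The authors deposited a table of raw read counts for 53819 gene symbols, with 1 column per library and no normalization. The submitters' processing notes name STAR, HISAT2, featureCounts, HTSeq and DESeq2 and the mouse build mm10 (GRCm38), without versions or roles. The annotation release is not given in the sources used here. Of the symbols, 49948 (92.8%) matched GENCODE vM21 by name and these held 98.9% of counts; coordinates and biotypes below come from vM21 on GRCm38. Total deposited counts per library ran from 30985905 to 34126329. Among counts of 1 to 10, even values made up between 70.5% and 73.2% in each library, and more genes had a count of 2 than of 1, for example 907 against 416 in water replicate 2. Separate counting of both mates of a read pair would give such a pattern, but this was not tested. Sequenced PCR products without molecular identifiers are not independent molecules, so intervals and floors (3 counts per library, 95% confidence) cover counting error only. If both mates of a pair were counted, counts are not independent, so the intervals are too narrow and the floors too low.

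Genes were filtered with filterByExpr of edgeR 4.0.16 at its defaults (minimum count 10, minimum total 15), which left 18788 genes with 99.4% of counts. Counts were scaled by TMM and tested with edgeR's quasi-likelihood test (glmQLFit with robust, glmQLFTest, group as the only term) under R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Levels are CPM, edgeR's read counts scaled to a common library size, on TMM-adjusted totals, given as mean ± SD over 2 libraries. The common biological coefficient of variation was 0.432, with 2 residual degrees of freedom per gene and a prior of 4.08. Nothing in the labels says that replicates came from separate mice, so p-values measure the spread between these libraries, which may be technical. The replicates were not duplicates of each other: a chi-square over genes gave 160 per degree of freedom for the water pair and 385 for the DSS pair. With 2 libraries against 2, an exact two-sided permutation test of a single gene cannot go below p = 0.333, so only tests that pool the spread across genes were used.

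Before the data were examined, 33 gene lists of pathways, cell markers and quality signals were fixed, together with the comparison, its test, the alternatives and the rule for naming genes. Lists were tested with camera of limma 3.58.1 (preset inter-gene correlation 0.01, two-sided, adjusted over the 33 lists), beside camera with an estimated correlation and fry. The naming rule took Ptgs2 and called prostaglandin genes, then up to 10 called genes per direction with the largest fold changes, at least 10 CPM in the higher group, both DSS libraries on one side of both water libraries and a named symbol (leaving out Riken, predicted and immunoglobulin or T cell receptor genes), and up to 4 members from each list with a called member; members of other lists appear only as values. It named Pbsn and Tcaf3 alone besides Ptgs2. After the data were seen, the same criteria were applied to the calls of DESeq2 1.42.0, which named 10 genes per direction, not all of which are described, and lists of pancreatic, prostate, adipocyte, smooth muscle, eosinophil receptor, hedgehog and Y-linked genes were added. List members beyond these were also chosen after their values were seen.

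The test was checked on 5 simulated data sets of the same 18788 genes, with the real means, library sizes and dispersions and 200 genes changed. edgeR called 0.8% of genes changed 2-fold, 50.4% at 4-fold, 68% at 8-fold and 75.6% at 16-fold, and 9.65% of its calls were unchanged genes. DESeq2 called 7.6%, 74.4%, 84.8% and 85.2%, and 31.7% of its calls were unchanged genes. When the neutrophil list alone was raised 4-fold, camera with the preset correlation called it in 5 of 5 simulations, with 1 call among 160 tests of other lists. With an estimated correlation it was called in 0 of 5, so the latter setting had little power in data simulated from these 4 libraries. Genes were drawn independently of each other in these simulations. The 1 call among 160 tests therefore does not show how often the preset setting calls lists falsely where members vary together.

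Alternatives were DESeq2 size factors, upper-quartile scaling, no count filter, a filter of CPM of at least 1 in 2 libraries, the DESeq2 Wald test, limma-voom, no robust step, a replicate block, an absolute log2 fold change of at least 1, and leaving out each library. Protein-coding genes alone had been planned from biotypes in the table; the table holds none, so vM21 biotypes were used. Added after the data were seen were a fit without immunoglobulin, mitochondrial and rRNA rows, a crossed block, and DESeq2 without each library. Figures were drawn with matplotlib 3.10.9.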

Results

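Gene expression was measured by RNA sequencing in samples labelled as primary eosinophils from the colon of wild-type mice. Eosinophils are granulocytes that reside in the intestinal wall. Eosinophil genes were low beside epithelial genes in every library: the receptor genes Siglecf, Ccr3 and Il5ra summed to 0.948 and 27.2 CPM in water and 35.0 and 116 CPM in DSS, and the epithelial gene Epcam stood at 804 and 524 CPM and 328 and 678 CPM. Control mice drank water; the others received 3% dextran sulfate sodium (DSS), a polymer that injures the colonic epithelium and causes colitis. Each group had 2 libraries. Total counts were 32041207 and 30985905 in water replicates 1 and 2, and 33015634 and 34126329 in DSS replicates 1 and 2. Between 21897 and 24221 gene symbols had at least 1 count. Immunoglobulin transcripts took 7.88% and 6.78% of counts in the water libraries and 31.8% and 8.31% in the DSS libraries. Mitochondrial transcripts took 14.6% and 13.8% in water and 8.62% and 9.92% in DSS. The exact 95% binomial interval of each of these shares was at most 0.0318 percentage points wide.

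The first question, from the title of the series, concerned COX-2, the inducible cyclooxygenase of prostaglandin synthesis, which Ptgs2 encodes (chromosome 1, 150100031 to 150108227, plus strand, GRCm38). Ptgs2 stood at 177 ± 151 CPM (SD, n = 2) in water and 756 ± 218 CPM (n = 2) in DSS. Water replicate 1 had 70.5 CPM and water replicate 2 had 284, against 910.0 and 601 in DSS replicates 1 and 2, so both DSS libraries lay above both water libraries. The log2 fold change was 2.09 (SE 0.70), and edgeR's quasi-likelihood test did not call it (adjusted p = 0.534, unadjusted p = 0.0238). DESeq2 called it (log2 fold change 2.08, adjusted p = 0.0126). That DESeq2 call ended without water replicate 1 (log2 fold change 1.41, adjusted p = 0.275) and without DSS replicate 1 (1.76, adjusted p = 0.326).

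The list of prostaglandin enzymes, transporters and receptors, which includes Ptgs2, did not pass its test. Of 21 tested members, Ptgs2 among them, 12 lay above 0 and 9 below, with a median log2 fold change of 0.07. No member was called by edgeR over all genes, none when adjusted over the list alone (1 without water replicate 2), and 1 by DESeq2, Ptgs2 itself. Camera did not call the list (adjusted p = 0.935). Hpgd, which degrades prostaglandins, had 60.7 ± 14.6 CPM in water and 27.3 ± 12.8 in DSS (log2 fold change -1.15, SE 0.40, edgeR adjusted p = 0.537). Hpgds, the haematopoietic prostaglandin D synthase, had a log2 fold change of -1.19 (SE 0.43, adjusted p = 0.558). Ptges, which makes prostaglandin E2, had 9.57 and 16.4 CPM in water and 19.9 and 14.3 CPM in DSS. The prostaglandin E2 receptor gene Ptger4 had a log2 fold change of 0.10 (SE 0.34).

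**Figure D1:**
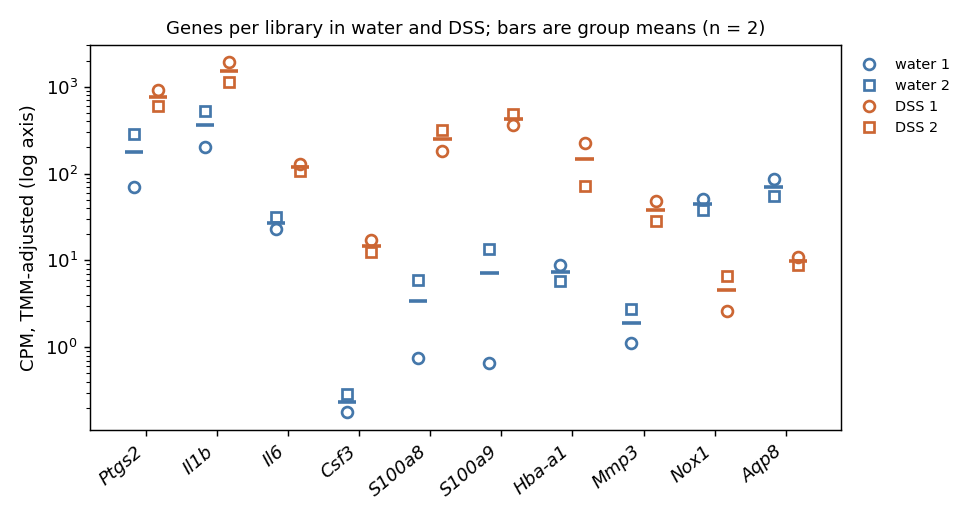
CPM on TMM-adjusted library sizes (log axis) of 10 genes in each library; circles are replicate 1, squares replicate 2, and bars the mean of each group (n = 2). For Ptgs2 both DSS libraries (601 and 910.0 CPM) lie above both water libraries (70.5 and 284 CPM).

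Across the transcriptome, the comparison of DSS with water asked which genes differ in these samples during colitis. edgeR called 3 genes, all lower in DSS, and none higher: Pbsn, Tcaf3 and 9530053A07Rik (each adjusted p = 0.0334). Pbsn, which encodes the prostate secretory protein probasin, lies on chromosome X (77837901 to 77853623, minus strand). It had 2786 and 1864 reads in water and 0 in both DSS libraries, at least 695-fold lower against a floor of 3 counts per library. Tcaf3 (chromosome 6, 42584866 to 42597692, minus strand) had 1361 and 1412 reads in water and 0 and 2 in DSS, a ratio of 1265 (counting interval 350 to 10448). 9530053A07Rik (chromosome 7, 28129466 to 28164811, plus strand), which was named after its values were seen, had 14349 and 15459 reads in water and 2 and 0 in DSS, a ratio of 13594 (3763 to 112254). All are annotated as protein-coding. These 3 calls were kept without each library in turn and were lost with limma-voom, which called 0 genes, and with a replicate block, which also called 0.

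At an unadjusted p under 0.05, edgeR had 951 genes higher and 636 lower, of 18788. The groups did not overlap for 3912 genes higher and 3515 lower in DSS, 39.5% of genes, where chance gives 33.3%. DESeq2 called 323 genes higher and 175 lower, 498 in all, of 19557 with an adjusted p; in simulated data 31.7% of DESeq2 calls were false. Without water replicate 1 DESeq2 called 166, without water replicate 2 832, without DSS replicate 1 173 and without DSS replicate 2 581. The edgeR total became 196 without water replicate 2, 7 without DSS replicate 1 and 9 without DSS replicate 2.

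The 10 genes named from the DESeq2 calls higher in DSS were Ngp, Chil3, Wfdc21, S100a8, Csf3, S100a9, Ltf, Hba-a1, Arg1 and Mmp3. S100a8 and S100a9, which encode the subunits of calprotectin, had 3.36 ± 3.71 and 7.17 ± 9.22 CPM in water and 248 ± 93.4 and 423 ± 79.5 CPM in DSS, log2 fold changes of 6.20 (SE 1.05) and 5.88 (SE 1.36). DESeq2's adjusted p was 1.2e-16 and 0.0181, and edgeR's 0.333 and 0.423. Csf3, the granulocyte colony-stimulating factor gene, had 0.235 ± 0.0807 CPM in water and 14.7 ± 3.27 in DSS (log2 fold change 5.94, SE 0.53; adjusted p = 0.100 with edgeR and 3.2e-17 with DESeq2). The neutrophil granule gene Ngp had 3 reads in the water libraries and 3635 in DSS, a ratio of 1328 (454 to 6445), and 3512 of these were in DSS replicate 2. Chil3, a chitinase-like secreted protein, had 2 and 1984 reads (ratio 1088, 301 to 8987), 1810 of them in DSS replicate 2, and Wfdc21 had 2 and 796 (436, 120 to 3609). Ltf (lactoferrin), Arg1 (arginase), the matrix protease gene Mmp3 and the haemoglobin gene Hba-a1 had log2 fold changes of 4.39, 4.36, 4.32 and 4.35. Without DSS replicate 2 the DESeq2 log2 fold change of Ltf fell from 4.37 to 2.06 (DESeq2 adjusted p = 0.261), that of Chil3 from 9.92 to 7.79, that of Ngp from 10.19 to 6.71 and that of Arg1 from 4.35 to 3.28. Without DSS replicate 1 that of Hba-a1 fell from 4.35 to 3.31. Without water replicate 2 those of S100a8, S100a9 and Mmp3 became 8.39, 9.35 and 5.10, and without water replicate 1 those of S100a8 and S100a9 became 5.36 and 4.94. Ngp, Chil3 and Wfdc21, with few reads in water, had 13.23, 12.38 and 7.70 without water replicate 1 and 9.20, 8.93 and 11.14 without water replicate 2. Without DSS replicate 1 Ngp, Chil3, Ltf and Arg1 had 11.14, 10.77, 5.24 and 4.98, and without DSS replicate 2 Wfdc21 and Hba-a1 had 8.08 and 4.96. Of these 10 genes, S100a8 and S100a9 were called by DESeq2 in 2 of the 4 fits that left out a library, Ngp and Ltf in 3, and the other 6 in all 4.

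Among the genes lower in DSS by the same rule, besides Pbsn and Tcaf3, were Nox1, Ang4, Mptx1, Cyp2d12, Tgm4, Clps and Rnase1. Nox1, an epithelial NADPH oxidase, had 44.7 ± 9.33 CPM in water and 4.59 ± 2.76 in DSS (log2 fold change -3.28, SE 0.50; adjusted p = 0.293 with edgeR and 3.4e-08 with DESeq2). Ang4, an angiogenin made by Paneth and goblet cells, had 22.3 ± 9.68 and 2.11 ± 1.22 CPM (log2 fold change -3.41, SE 0.57; DESeq2 adjusted p = 1.0e-06). Both were called by DESeq2 without each library in turn. Mptx1, a pentraxin, and Cyp2d12, a cytochrome P450, had log2 fold changes of -5.32 and -3.35 and were called in 2 and 3 of those fits. Without DSS replicate 1 the edgeR log2 fold changes of Mptx1 and Ang4 became -8.25 and -4.16, and without DSS replicate 2 those of Mptx1 and Nox1 became -4.40 and -4.08. Without water replicate 1 those of Mptx1 and Cyp2d12 became -4.40 and -2.42. Tgm4, a prostate transglutaminase, had 2407 and 2481 reads in water and 0 and 6 in DSS (edgeR adjusted p = 0.0660). The pancreatic gene Clps (colipase) and the ribonuclease gene Rnase1 had 15328 and 13828 reads in water replicate 1 against 44 and 249 in water replicate 2. Rnase1 had 0 reads in both DSS libraries. Of the 4 fits that left out a library, DESeq2 called Clps in 1, Tgm4 in 2 and Rnase1 in 3.

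Among the fixed lists, camera with the preset correlation called 25 of 33, 21 higher and 4 lower in DSS. With an estimated correlation 0 were called (lowest adjusted p = 0.402), and 2 lists had an unadjusted p under 0.05. Fry called 0 in either form, with lowest adjusted p of 0.205 for a shift one way and 0.0859 for change either way. Over all genes edgeR called no member of any list. Of the 25 calls, 14 were kept without each library in turn.

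The number of list members called when adjusted over the list alone depended on the test. In the paragraphs after this one, counts over the list alone are edgeR's unless another test is named. Calls by DESeq2 there are adjusted over all genes unless said otherwise. Of the NF-kB targets, 0 were higher with edgeR, 15 with DESeq2, 17 with limma-voom, 17 with the crossed block, and 11 without immunoglobulin, mitochondrial and rRNA genes or with protein-coding genes. Of the eosinophil identity list, 0 were higher with edgeR, 7 with DESeq2 or limma-voom and 12 with the replicate block. For chemokine receptors the count was 0 with edgeR, 9 with DESeq2 or the replicate block and 6 with limma-voom. For pattern recognition it was 8 with edgeR and 0 with the replicate block, and for T cell, NK cell and innate lymphoid markers 13 and 7. For mast cell markers it was 2 with edgeR, 9 with DESeq2 and 10 with the replicate block, and for cytokines 5, 10 and 6. For B cell and plasma cell markers it was 0 with edgeR and 7 with DESeq2, and for the activated intestinal eosinophil list 0 and 6. The same count without a count filter was 17 for NF-kB targets, 13 for eosinophil identity and 12 for mast cell markers. For prostaglandin genes it was 0 with edgeR and 1 higher with DESeq2. With the crossed block or without a count filter, 1 prostaglandin gene was higher and 2 were lower. For immediate early and heat shock genes the count was 0 with edgeR, 5 with DESeq2 and 4 with the crossed block. For apoptosis and survival genes it was 0, 4 and 4, and for glycolysis 0, 2 and 0.

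**Figure D2:**
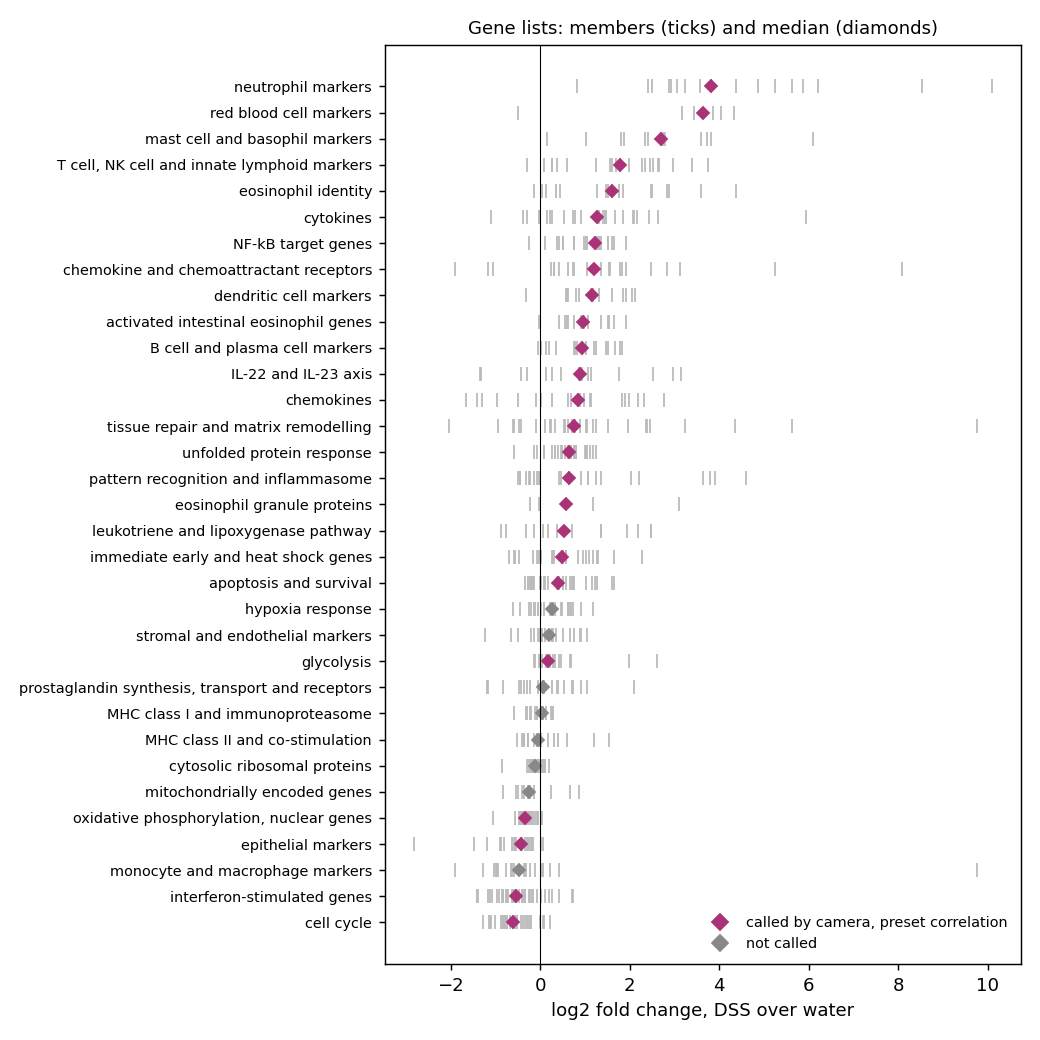
Log2 fold change (DSS over water) of the tested members of each of the 33 gene lists (ticks) and their median (diamonds, coloured where camera with the preset correlation called the list). The highest median is 3.83 for neutrophil markers and the lowest -0.59 for cell cycle genes.

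Neutrophil markers rose as a list (camera adjusted p = 5.3e-27; adjusted p = 0.402 with an estimated correlation). All 17 tested members lay above 0, with a median log2 fold change of 3.83; 12 were higher when adjusted over the list alone and 10 by DESeq2. Lcn2, the iron-scavenging lipocalin, had 16.8 ± 2.78 CPM in water and 89.1 ± 50.9 in DSS, and Csf3r, the receptor for granulocyte colony-stimulating factor, had 35.6 ± 22.8 and 263 ± 218. The log2 fold change of Csf3r was 2.89 with all libraries, 1.59 without DSS replicate 1, 3.55 without DSS replicate 2 and 3.76 without water replicate 2, and that of Lcn2 was 2.41, and 1.66 without DSS replicate 2. The median of the list became 8.39 without water replicate 2 and 4.66 without DSS replicate 1. Without DSS replicate 2, 8 were higher over the list alone.

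Cytokine genes rose as a list (camera adjusted p = 9.2e-12; adjusted p = 0.402 with an estimated correlation), with 21 of 25 members above 0 and a median log2 fold change of 1.28 (0.61 without water replicate 1). Adjusted over the list alone, 5 were higher, namely Csf3, Il6, Il33, Il11 and Lif, and DESeq2 called 7. Il6 had 27.3 ± 6.28 CPM in water and 118 ± 13.9 in DSS (log2 fold change 2.11, SE 0.30, adjusted p = 0.00517 over the list alone and 0.281 over all genes with edgeR). Il1b, the gene of interleukin-1 beta, had 362 ± 222 and 1523 ± 565 CPM, with an edgeR adjusted p of 0.0504 over the list alone and a DESeq2 adjusted p of 0.00264, a DESeq2 call that ended without water replicate 1 (adjusted p = 0.194) and without DSS replicate 1 (adjusted p = 0.221). Neutrophil markers stood higher in the same libraries as this list, at a summed 63.7 and 208 CPM in water and 1389 and 2021 CPM in DSS. The list-alone count was 3 without water replicate 1, 15 without water replicate 2, and 2 without either DSS library.

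Chemokine genes rose as a list (camera adjusted p = 0.000343; adjusted p = 0.547 with an estimated correlation), a call lost without water replicate 1 (adjusted p = 0.435). Adjusted over the list alone, the neutrophil attractants Cxcl5 (log2 fold change 2.76, SE 0.35) and Cxcl1 (1.83, SE 0.43) were higher and Ccl8 (-1.65, SE 0.38) was lower; Cxcl1 had 2.43 without water replicate 2; the counts were 12 higher without water replicate 2 and 1 without any other library, and Ccl8's call ended without either DSS library. Ccl11, the gene of the eosinophil attractant eotaxin, had 60.6 ± 21.9 CPM in water and 61.3 ± 13.3 in DSS. Chemokine and chemoattractant receptors rose as a list (camera adjusted p = 1.1e-06; adjusted p = 0.516 with an estimated correlation), with 19 of 22 members above 0, none called over the list alone, and 3 higher and 1 lower by DESeq2. Over the list alone, 5 were higher and 2 lower without water replicate 1, and 13 were higher without water replicate 2. In the same libraries neutrophil markers summed to 63.7 and 208 CPM (water) and 1389 and 2021 CPM (DSS).

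Pattern recognition and inflammasome genes rose as a list (camera adjusted p = 3.6e-06; adjusted p = 0.402 with an estimated correlation), with 15 of 25 above 0. Adjusted over the list alone, 8 were higher, and DESeq2 called 4. They included Clec4e, a lectin receptor (log2 fold change 3.63, SE 0.81), Trem1 (4.61, SE 1.17), Cd14 (1.37, SE 0.35) and Nlrp3 (2.20, SE 0.65). Without water replicate 1 Clec4e, Trem1 and Nlrp3 had 2.84, 3.64 and 1.5, and without water replicate 2 they had 5.32, 8.12 and 3.47. That count was 4 without water replicate 1 and 0 without either DSS library. Tissue repair and matrix genes rose as a list (camera adjusted p = 5.0e-07; adjusted p = 0.453 with an estimated correlation). Adjusted over the list alone, 5 were higher (Timp1, Chil3, Arg1, Ereg and Mmp8) and Retnla was lower (log2 fold change -2.04, SE 0.50); 14 were higher without water replicate 2, and Retnla's call ended without water replicate 1 and without DSS replicate 2. The log2 fold change of Retnla was -2.83 without DSS replicate 1, and that of Ereg was 2.39 with all libraries and 3.01 without water replicate 2. Neutrophil markers, among them Mmp8 of this list, moved in the same libraries as both lists, with a summed 63.7 and 208 CPM in water and 1389 and 2021 CPM in DSS. Ereg, the growth factor epiregulin, had 20.9 ± 10.3 CPM in water and 109.8 ± 1.93 in DSS.

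Eosinophil genes were low in all libraries. Siglecf, Ccr3 and Il5ra, the surface receptors used to identify the cell, had 28, 4 and 0 reads in water replicate 1 and 419, 413 and 100 in water replicate 2. They had 299, 542 and 99 reads in DSS replicate 1 and 1269, 2350 and 452 in DSS replicate 2. Epcam, an epithelial gene, had 8820 to 27129 reads per library. The identity list rose (camera adjusted p = 1.7e-09; adjusted p = 0.453 with an estimated correlation), with 17 of 18 members above 0, a median log2 fold change of 1.61 (1.03 without water replicate 1 and 2.45 without water replicate 2), 0 called by edgeR over all genes or over the list alone and 4 by DESeq2. Without water replicate 2, 14 were higher over the list alone. Several members, such as Itgb2 and Csf2rb, are expressed by other myeloid cells. In the same libraries neutrophil markers summed to 63.7 and 208 CPM (water) and 1389 and 2021 CPM (DSS). Mast cell and basophil markers summed to 48.4 and 165 CPM (water) and 551 and 510 CPM (DSS). Of the granule protein list 4 of 10 genes were tested, 2 above 0 and 2 below. The list summed to 206 and 203 CPM in water and 157 and 279 CPM in DSS. Of this sum Cd63, which other cells also express, alone took 100 CPM or more in every library. Camera called it (adjusted p = 0.0494; adjusted p = 0.453 with an estimated correlation), and the call was lost without DSS replicate 2 (adjusted p = 0.0892), with limma-voom, with the replicate block and with the crossed block. Prg2, the major basic protein gene, was higher when adjusted over the list alone (1.18 ± 0.595 CPM in water and 10.2 ± 2.36 in DSS); without DSS replicate 1 the count was 3.

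The activated intestinal eosinophil list and the NF-kB target list rose (camera adjusted p = 1.2e-06 and 5.9e-12). The adjusted p was 0.453 and 0.402 with an estimated correlation. NF-kB targets lay above 0 in 23 of 24 members with a median log2 fold change of 1.23; none was called over the list alone and 5 by DESeq2. Tnfaip3, a feedback inhibitor of NF-kB and a member of both lists, had 297 ± 226 CPM in water and 1116 ± 62.9 in DSS (edgeR adjusted p = 0.525, DESeq2 adjusted p = 0.0130). That DESeq2 call ended without water replicate 1 (adjusted p = 0.314), without DSS replicate 1 (0.121) and without DSS replicate 2 (0.0702). In the activated list 13 of 14 members lay above 0, with none called over the list alone and 1 by DESeq2. Without water replicate 2, 12 NF-kB targets and 7 of the activated list were higher over the list alone. Neutrophil markers moved the same way in the same libraries, from a summed 63.7 and 208 CPM in water to 1389 and 2021 CPM in DSS.

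The IL-22 and IL-23 axis rose as a list (camera adjusted p = 0.00317; adjusted p = 0.402 with an estimated correlation), a call lost without DSS replicate 2 (adjusted p = 0.0807). No member was called over the list alone and 1 by DESeq2, Il23a (1.26 ± 1.36 CPM in water, 9.83 ± 3.68 in DSS). Without water replicate 2, 3 members were higher over the list alone. Il22 itself had 1.08 ± 1.44 CPM in water and 3.70 ± 1.66 in DSS (log2 fold change 1.77, SE 1.30, edgeR adjusted p = 0.784). The leukotriene and lipoxygenase list rose (camera adjusted p = 0.00512; adjusted p = 0.547 with an estimated correlation), a call lost without DSS replicate 2 (adjusted p = 0.611); no member was called over the list alone and 2 by DESeq2, Fpr2 and Alox5ap. Without water replicate 1 neither was called by DESeq2 (adjusted p = 0.191 and 0.381), nor was Il23a (0.197); Il23a and Fpr2 were not called without DSS replicate 1 (0.646 and 0.373), nor Alox5ap without DSS replicate 2 (0.300). Fpr2 and Alox5ap are expressed by myeloid cells, and neutrophil markers were higher in the same libraries, at 63.7 and 208 CPM in water and 1389 and 2021 CPM in DSS. Over the leukotriene list alone, 5 were higher without water replicate 2 and 1 without DSS replicate 2.

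Markers of other immune and blood cells were also higher in DSS. T cell, NK cell and innate lymphoid markers rose (camera adjusted p = 1.2e-15; adjusted p = 0.402 with an estimated correlation), with 21 of 22 above 0, 13 higher over the list alone and 8 by DESeq2. Cd8a had 1.46 ± 0.244 CPM in water and 11.5 ± 2.99 in DSS, and Trac, the T cell receptor alpha constant gene, 2.33 ± 1.24 and 14.7 ± 5.86. Over the list alone the count was 6 without water replicate 1 and 0 without DSS replicate 1. Mast cell and basophil markers rose (camera adjusted p = 9.8e-12; adjusted p = 0.402 with an estimated correlation), with 13 of 13 above 0, and the mast cell protease gene Mcpt4 and Fcer1a higher over the list alone; that count was 12 without water replicate 2, 3 without water replicate 1 or DSS replicate 1 and 0 without DSS replicate 2. Dendritic cell markers rose (camera adjusted p = 4.4e-07; adjusted p = 0.402 with an estimated correlation), with Flt3 higher over the list alone, a call that ended without water replicate 1 or DSS replicate 1; without water replicate 2 the count was 8. Red blood cell markers rose (camera adjusted p = 4.7e-14; adjusted p = 0.402 with an estimated correlation), with 5 of 6 tested members higher over the list alone and by DESeq2. Without DSS replicate 2, 1 red blood cell marker was lower over the list alone.

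B cell and plasma cell markers rose as a list (camera adjusted p = 0.000163; adjusted p = 0.547 with an estimated correlation), a call lost without water replicate 1 and without DSS replicate 1 (highest adjusted p = 0.387). Their summed level was 51925 ± 8855 CPM in water, 291391 CPM in DSS replicate 1 and 60179 CPM in DSS replicate 2. No member was called over the list alone with edgeR, or over all genes by DESeq2. Over the list alone DESeq2 had 7 members higher. Monocyte and macrophage markers (adjusted p = 0.108) and stromal and endothelial markers (adjusted p = 0.393) were not called by camera. Without water replicate 1 the monocyte and macrophage list was called lower (adjusted p = 1.7e-07) and 8 members were lower over the list alone; it was also called lower with limma-voom (adjusted p = 0.0249) and from the DESeq2 fit. Chil3 was higher over that list alone with all libraries, but not without water replicate 2 or with limma-voom. The stromal and endothelial list was called higher without water replicate 2 (adjusted p = 0.0367) and without DSS replicate 1 (adjusted p = 0.00937).

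**Figure D3:**
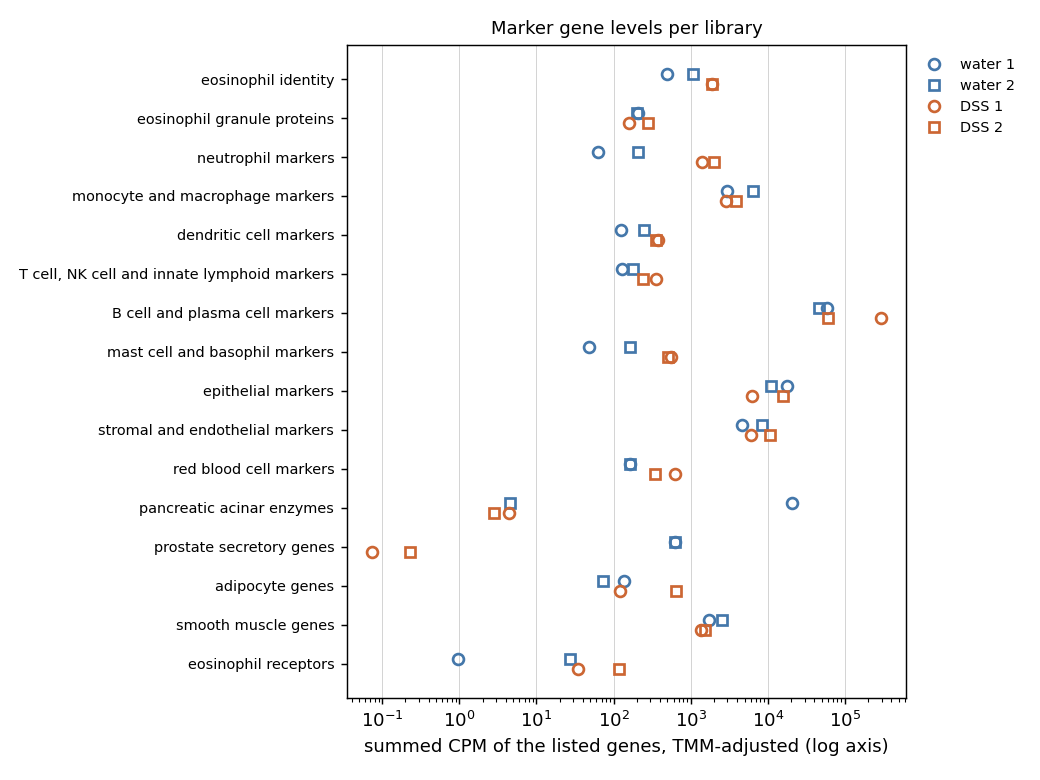
Summed CPM (TMM-adjusted, log axis) of marker genes per library; circles are replicate 1, squares replicate 2. Neutrophil markers lie at 63.7 and 208 CPM in water and 1389 and 2021 CPM in DSS, and epithelial markers lie between 6269 and 17958 CPM in all libraries.

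Lists that fell comprised epithelial, cell cycle, interferon-stimulated and oxidative phosphorylation genes. Epithelial markers fell (camera adjusted p = 6.6e-05; adjusted p = 0.559 with an estimated correlation), a call lost without DSS replicate 1 (adjusted p = 0.675). With all libraries, 21 of 23 lay below 0, with a median log2 fold change of -0.43 (-1.17 without DSS replicate 2), and Aqp8, a water channel of surface colonocytes, was lower over the list alone and by DESeq2 (70.4 ± 22.5 CPM in water, 9.95 ± 1.56 in DSS). Cell cycle genes fell (camera adjusted p = 2.8e-08; adjusted p = 0.402 with an estimated correlation), with 28 of 32 below 0, none called over the list alone, and Stmn1 called by DESeq2 (60.5 ± 9.09 and 25.0 ± 2.03 CPM), a DESeq2 call that was lost whichever library was left out (lowest adjusted p = 0.123, without water replicate 2). Interferon-stimulated genes fell (camera adjusted p = 3.8e-06; adjusted p = 0.559 with an estimated correlation), with 33 of 41 below 0, a call lost without DSS replicate 2 (adjusted p = 0.517). Nuclear oxidative phosphorylation genes fell (camera adjusted p = 0.00656; adjusted p = 0.725 with an estimated correlation), a call lost without water replicate 1 and without DSS replicate 1 (highest adjusted p = 0.868). Their summed level was 6719 and 4735 CPM in water and 3539 and 5884 CPM in DSS, beside 17958 and 11141 and 6269 and 15787 CPM for epithelial markers; both were lowest in DSS replicate 1, where immunoglobulin transcripts took 31.8% of counts. Neither the interferon-stimulated nor the oxidative phosphorylation list had a member called over the list alone or by DESeq2.

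Stress and survival lists rose. The unfolded protein response had 23 of 26 members above 0 (camera adjusted p = 0.000343; adjusted p = 0.556 with an estimated correlation), a call lost without DSS replicate 1 (adjusted p = 0.123). Its summed level was 11162 CPM in that library and 5170, 7088 and 7384 CPM in the others, and B cell and plasma cell markers summed to 291391 CPM in that library and 45664 to 60179 CPM in the others. Immediate early and heat shock genes, which respond to handling of tissue, were called (camera adjusted p = 0.000505; adjusted p = 0.559 with an estimated correlation), but not without water replicate 1 (adjusted p = 0.575). Apoptosis and survival genes rose (camera adjusted p = 0.00297, and 0.402 with an estimated correlation), with Pim1 called by DESeq2. This list summed to 1682 and 2174 CPM in water and 3210 and 3144 CPM in DSS. Neutrophil markers rose in the same libraries, from 63.7 and 208 CPM in water to 1389 and 2021 CPM in DSS. Glycolysis genes rose (camera adjusted p = 0.0329; adjusted p = 0.617 with an estimated correlation), a call lost without DSS replicate 2 (adjusted p = 0.687), with Slc16a3 called by DESeq2. The DESeq2 call of Pim1 was kept without water replicate 2 alone (adjusted p = 8.5e-06), and that of Slc16a3 ended without DSS replicate 1 (adjusted p = 1.00). None of these 4 lists had a member called over the list alone with edgeR. Without water replicate 2 the count was 5 for immediate early genes, 2 for glycolysis and 1 for apoptosis.

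The lists of hypoxia (adjusted p = 0.0827), cytosolic ribosomal proteins (0.382), mitochondrially encoded genes (0.382) and MHC class I (0.677) and class II (0.630) were not called by camera, and none had a member called over the list alone or by DESeq2. Hypoxia was called higher with limma-voom (adjusted p = 0.0304) and without DSS replicate 1 (adjusted p = 0.00105) and MHC class II without water replicate 2 (adjusted p = 0.00887), where 3 class II members and 1 hypoxia member were higher over the list alone. For MHC class I the median log2 fold change was 0.03 and the mean -0.04; for class II they were -0.04 and 0.12.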

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

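Tests without immunoglobulin, mitochondrial and rRNA genes, with vM21 protein-coding genes, with a crossed block and with DESeq2 without each library were chosen after the results were seen. The 3 edgeR calls, all lower in DSS, were kept with DESeq2 size factors, upper-quartile scaling, the CPM filter, no robust step and the fold minimum. Without a count filter 1051 genes were called (710 higher, 341 lower), with infinite fitted prior degrees of freedom against 4.08 with the filter; whether that was the cause was not tested. The DESeq2 Wald test called 498 (323 higher, 175 lower) and limma-voom 0 (0 lower); the cause was not tested. A replicate block called 0 (0 lower), but the replicates only share a number (r = -0.104 across genes), and the crossed block called 44 (29 higher, 15 lower). Leaving out each library gave 3 to 196 calls, 0 to 123 higher and 3 to 73 lower; the lone library of a group was assumed to vary like the other group. The Ptgs2 log2 fold change kept its sign in every alternative and was called with 2.09 without the filter (adjusted p = 0.0014) and 2.08 with DESeq2 (adjusted p = 0.0126), while the other alternatives with all libraries gave adjusted p of 0.131 to 0.752; leaving out each library gave 1.38 to 3.43 (adjusted p 0.0972 to 1.00). Camera called 25 lists, 24 to 26 in alternatives with all libraries and 20 to 27 without each library, but 0 with an estimated correlation and 0 with fry; in simulated data the estimated correlation had called 0 of 5 raised lists. Of 9 lists of other cell types, 6 were higher in both DSS libraries, and 5 to 7 in alternatives. The summed epithelial level had a log2 ratio of -0.40 and turned to 0.11 without DSS replicate 1, within a range of -1.21 to 0.11 over the libraries left out. Among the other values 654 kept their direction and side of the threshold, 64 passed it, 72 no longer did and 1, the epithelial level, reversed. In 3 more, summed levels of cell type lists that camera did not call, the log2 ratio also changed sign. The planned protein-coding alternative needed biotypes that the table does not give, so it was not run as planned. Depth limited genes near the floor of 3 counts per library.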

Other observations

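All tests in this part were chosen after the results were seen. Genes of other colonic compartments stood apart from the lists described so far. Of 4 stromal genes of the hedgehog pathway, picked after their values were seen and not tested as a set, DESeq2 called 3 lower in DSS. Hhip had 125 ± 41.3 CPM in water (n = 2) and 15.4 ± 0.868 in DSS (log2 fold change -3.03, DESeq2 adjusted p = 3.7e-11), and Gli1 had 40.5 and 70.2 CPM in water and 9.49 and 4.61 CPM in DSS (-2.98, DESeq2 adjusted p = 7.7e-07). Foxl1 had a log2 fold change of -2.36 (DESeq2 adjusted p = 0.0138), and Ptch1, which was not called, had -1.13 (DESeq2 adjusted p = 0.186). The DESeq2 calls of Hhip and Gli1 were kept without each library in turn, with Gli1 at -3.59 without DSS replicate 1, and that of Foxl1 was lost whichever library was left out. The crypt stem cell genes Lgr5 and Ascl2 had 331 and 92 reads and 179 and 107 reads in water, and 0 and 18 reads and 0 and 20 reads in DSS (DESeq2 adjusted p = 0.00148 and 0.0190). Both DESeq2 calls ended without either water library, and that of Ascl2 also without DSS replicate 1 (lowest adjusted p = 0.200). edgeR called none of these genes (lowest adjusted p = 0.217). The DESeq2 log2 fold change of Lgr5 was -4.58 with all libraries. It was -3.38 without water replicate 1, -5.26 without water replicate 2, -3.60 without DSS replicate 1 and -9.82 without DSS replicate 2.

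Single libraries stood apart in genes of other organs. Pancreatic digestive enzymes summed to 20572 CPM in water replicate 1, 2.17% of its counts, and to at most 4.53 CPM in the other libraries; Ctrb1, a chymotrypsinogen gene, had 181953 reads there and 0 elsewhere. Adipocyte genes summed to 653 CPM in DSS replicate 2 and to 72.3 to 136 CPM in the others. Smooth muscle genes summed to 1750.0 and 2576 CPM in water and 1374 and 1555 CPM in DSS. Y-linked genes had reads in all 4 libraries, with sums of 229 to 284 CPM.

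The genes with the lowest edgeR p-values are secretory genes of the prostate, with both water libraries at 619 CPM summed and both DSS libraries near 0. General loss of colonic epithelium with DSS is argued against for Pbsn, Tcaf3, 9530053A07Rik and Tgm4, whose weakest log2 fold change was -9.51, since the lowest among 23 epithelial markers was -2.82; loss of a single epithelial cell type is not excluded, as Mptx1 had -5.32 and Lgr5 -4.53. A candidate explanation is prostate RNA in the water libraries: 5 of 8 further prostate genes had at least 10 reads in both water and fewer than 10 in both DSS libraries, 2 had no reads in any library, and 1, Azgp1, had reads in all. A more distal stretch of colon in the water libraries cannot be told apart from prostate RNA. Hoxb13 is expressed in both distal colon and prostate, and no label gives the position. Its edgeR log2 fold change was -2.93 (adjusted p = 0.401 with edgeR and 1.3e-05 with DESeq2). With a library left out its DESeq2 log2 fold change ran from -3.82 (without DSS replicate 2) to -2.37 (without water replicate 1). The isolation of the cells is not given in the sources used here, so no sorting step that would remove such RNA can be named.

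Transcripts of other colonic cells lay far above eosinophil genes in all 4 libraries. Immunoglobulin transcripts taking the counts cannot explain why Epcam lay above the summed Siglecf, Ccr3 and Il5ra, since they scale these genes alike. The smallest ratio of Epcam to that sum, 5.86, is the same by construction with and without immunoglobulin transcripts. The values show that the libraries held much RNA of genes typical of other colonic cells. Of 60 epithelial, B and plasma cell, and stromal genes, 28 stood at 100 CPM or more in every library. Of 28 eosinophil genes, 2 did, Cd24a and Cd63, which other cells also express. How RNA of other colonic cells came into these libraries stays open, since high levels of such genes are the pattern itself. Among the most abundant were Igha at 27972 ± 5127 CPM in water and Krt8 at 2307 ± 778. No biological explanation was tested.

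Ptgs2 was higher in both DSS libraries. Leaving out immunoglobulin, mitochondrial and rRNA genes shifted log2 fold changes by a median of 0.006, and Ptgs2 stood at 2.10. As the shift was nearly alike for all genes, this fit cannot decide whether scaling by the immunoglobulin share raised Ptgs2. Before any scaling Ptgs2 had 2380 and 9718 reads in water and 24453 and 21134 in DSS. Library totals ran from 30985905 to 34126329. These unscaled reads argue against scaling by the immunoglobulin share as the source of the higher Ptgs2 level. A larger eosinophil share in DSS (log2 ratio of summed receptor genes 2.42) and neutrophil RNA in DSS (log2 ratio of summed markers 3.65) cannot be told apart from a change within eosinophils, because all move with the groups. Within water all were lower in replicate 1. Within DSS, Ptgs2 (910.0 and 601 CPM) ran opposite to the receptor genes (35.0 and 116) and the neutrophil markers (1389 and 2021). The leukocyte gene Ptprc had 71.0 and 217 CPM in water and 469 and 319 CPM in DSS. Its log2 fold change was 1.45 (edgeR adjusted p = 0.580), and its relation to Ptgs2 was not tested. The receptor ratio was 1.47 without water replicate 1, 6.31 without water replicate 2, 3.04 without DSS replicate 1 and 1.31 without DSS replicate 2, the neutrophil ratio 3.00 without water replicate 1 and 4.75 without water replicate 2, and Siglecf alone did not separate the groups (12.2 CPM in water replicate 2 and 11.1 CPM in DSS replicate 1). The DSS treatment itself stays open as an untested biological explanation.

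The 4 libraries can be split into pairs in 3 ways, too few for a share under 0.05. DESeq2 called 498 genes for the real split, and 1 of the 3 splits, the real one, gave as many; the highest of the others gave 56.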
